A study of Mus musculus with 12 samples.

How the data were processed

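RNA levels were measured in 12 mouse embryonic stem cell samples carrying a MERVL-driven tdTomato reporter, in 4 groups of 3. The groups, taken from the sample titles, were parental cells, cells with Dppa2 and Dppa4 knocked out, and knockout cells with wild-type or mutant Dppa2 and Dppa4 fused to GFP. That the mutant is SUMO-deficient comes from the series' design text. Per the labels' protocols the cells were grown on gelatin in medium with serum replacement and LIF, the add-back cells were transfected by lipofection and sorted for GFP, RNA was taken with TRIzol, and biotin-labelled cDNA was made with the Affymetrix WT Plus kit. The deposited values are log2 signals, 1 per probe set and array, which the authors had normalized; per the submitters' processing notes the Transcriptome Analysis Console was used. Its version, the background correction, the summarization and the genome build are not given in the sources used here, so no coordinates are printed, and any compression of low signals by that step carries into the differences below. That the scale is log2 was read from the range of the values. No detection calls were used, and for that reason low values cannot be separated from background. The arrays had lower quartiles of 2.36 to 2.47 and medians of 3.73 to 3.88, and no pair of the 12 held identical values.

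Of 41345 probe sets, 23521 had 1 gene symbol in GEO's annotation of the array, 1814 had several and 16010 had none. The Entrez identifiers of 23328 single-symbol probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. A probe set with 1 symbol stood for its gene, and of several probe sets the one with the highest mean over all arrays was used, which left 22180 genes, 1082 of them with more than 1 probe set. Probe sets with no symbol or several were tested apart and are not named.

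Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, 1 mean per group, all 12 arrays sharing the estimate of spread). Two-sided p-values were adjusted by Benjamini-Hochberg over the 22180 genes of a comparison, with a threshold of 0.05 and no fold limit. There were 6 comparisons: knockout against parental, each add-back against knockout, the add-backs against each other and each add-back against parental. The 17 gene lists, with 446 of 490 entries measured, were the 2C-like program, germline and meiosis, naive pluripotency, formative and primed pluripotency, endoderm, mesoderm, neuroectoderm, trophectoderm, fibroblast markers, interferon response, p53 targets, ATF4 and unfolded protein response, immediate early and heat shock, imprinted genes, SUMO pathway and silencing, X inactivation and Y-linked genes, and the Dppa family. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 17 lists of a comparison. Means of lists were compared by exact two-sided permutation tests, for which 0.1 is the smallest p with 3 arrays per group. Values per gene are log2 differences with their limma SE. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

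The groups, lists, tests of the comparisons, alternatives and the rule for naming genes were fixed before the data were examined. Some tests of explanations were chosen later, as stated with them. The rule took the 10 largest rises and falls past the threshold whose groups did not overlap (5 for the add-backs against parental cells), leaving out predicted, uncharacterised, olfactory, vomeronasal, microRNA and small nucleolar RNA genes outside the lists, or the 3 genes of smallest p where fewer than 3 passed. It added Dppa2 and Dppa4, up to 4 members of each list by smallest p, and members of a gene set already named. The alternatives were the replicate number as a block, repeated quantile normalization, median centring, leaving out genes below percentile 25 of signal, eBayes with trend and robust variances, fits of the 6 arrays compared, a 2-fold limit, the mean of a gene's probe sets, all probe sets, array weights, fry, an estimated correlation, averaged gene families, and leaving out each array.

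The titles number the replicates 1 to 3 in each group, and the labels do not say what a number stands for. Deviations of same-numbered arrays from their group means correlated above 0.1 in every pair for knockout against parental (0.36, 0.15 and 0.42), for the add-backs against each other (0.40, 0.21 and 0.47), and for wild-type (0.33, 0.15 and 0.31) and mutant add-back (0.33, 0.13 and 0.36) against parental cells, so the numbers were taken to pair those arrays. For wild-type and mutant add-back against knockout, replicate 2 stayed below that limit (0.06 and 0.08), so those arrays were not taken as paired. For comparisons that share the knockout arrays, 100 simulations of unchanged groups gave the correlation and covariance that sharing alone produces.

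The tests were tried on simulated data for the 22180 genes, with 50 genes changed at each size. Of changes of 0.5, 1, 2 and 3 (log2), 12%, 86%, 100% and 100% were recovered for knockout against parental, 16%, 90%, 100% and 100% for wild-type add-back against knockout, 10%, 92%, 100% and 100% for mutant add-back against knockout, and 12%, 92%, 100% and 100% for the add-backs against each other. False calls numbered 10, 11, 11 and 6 in that order.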

Results

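Transcript levels were measured on 12 Affymetrix arrays in 4 groups of 3 mouse embryonic stem cell samples. The cells carried a red fluorescent reporter driven by MERVL, an endogenous retrovirus that is active in 2-cell embryos. The groups were the parental reporter cells, cells with Dppa2 and Dppa4 knocked out (KO), and KO cells given back both proteins fused to GFP, either wild-type (KO+WT) or in a form that cannot be modified by SUMO (KO+Mut). Dppa2 and Dppa4 are DNA-binding proteins of early embryos and pluripotent cells, and SUMO is a small protein that is attached to other proteins after translation. The add-back cells had been transfected and sorted for GFP, which the labels do not say of the KO or parental cells, so that only the comparison of the add-backs with each other was matched for those steps. Median array signals lay between 3.73 and 3.88 (log2), and the 66 pairs of arrays correlated with r between 0.976 and 0.994 across genes. The labels call the arrays of a group biological replicates and say no more, so p-values measure the spread between them. The number of arrays limited the precision, with a median 95% half-width of 0.344 (log2) for a difference between groups.

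The targeted genes were read first. Dppa2 signal (log2) was 9.35, 9.81 and 10.17 on parental replicates 1, 2 and 3, against 8.13, 8.69 and 8.63 on the KO replicates. It was 10.79, 11.34 and 11.11 with wild-type add-back and 11.12, 11.30 and 11.17 with mutant add-back. Dppa4 was 8.24, 8.58 and 8.56 in parental cells, 7.92, 7.63 and 7.31 in KO cells, 10.09, 10.58 and 10.49 in KO+WT and 10.55, 10.67 and 10.39 in KO+Mut. Dppa2 fell by 1.29 in KO cells (SE 0.21, limma adjusted p = 0.0259), while the Dppa4 difference of -0.84 (SE 0.18) had an adjusted p of 0.102. Both genes lay between percentiles 87.3 and 95.4 of all probe sets on the KO arrays. The position of the probes relative to the deleted sequence is not given in the sources used here, and probes outside it check nothing. Against KO cells, Dppa2 rose by 2.60 with wild-type and 2.72 with mutant add-back, and Dppa4 by 2.77 and 2.92 (highest adjusted p = 2.83e-05). Relative to parental cells Dppa2 was 1.31 and 1.42 higher and Dppa4 1.93 and 2.08 higher, with adjusted p of 0.0154, 0.00529, 0.000253 and 9.05e-05. The add-backs differed from each other by 0.12 for Dppa2 (SE 0.21) and 0.15 for Dppa4 (SE 0.18), with adjusted p = 1 for both. The Dppa2 call in KO cells was kept without parental replicate 1 and lost without any other of its arrays (adjusted p = 0.131 and 0.139 without parental replicates 2 and 3, and 0.112, 0.068 and 0.0669 without KO replicates 1, 2 and 3), and it was lost when the 6 arrays of these groups were fitted alone (adjusted p = 0.126). The call of Dppa2 in KO+WT above parental cells was lost in that fit of 6 arrays (adjusted p = 0.0839), without parental replicates 1 and 2 (0.0568 and 0.0612) and without KO+WT replicates 2 and 3 (0.0772 and 0.0564).

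**Figure D1:**
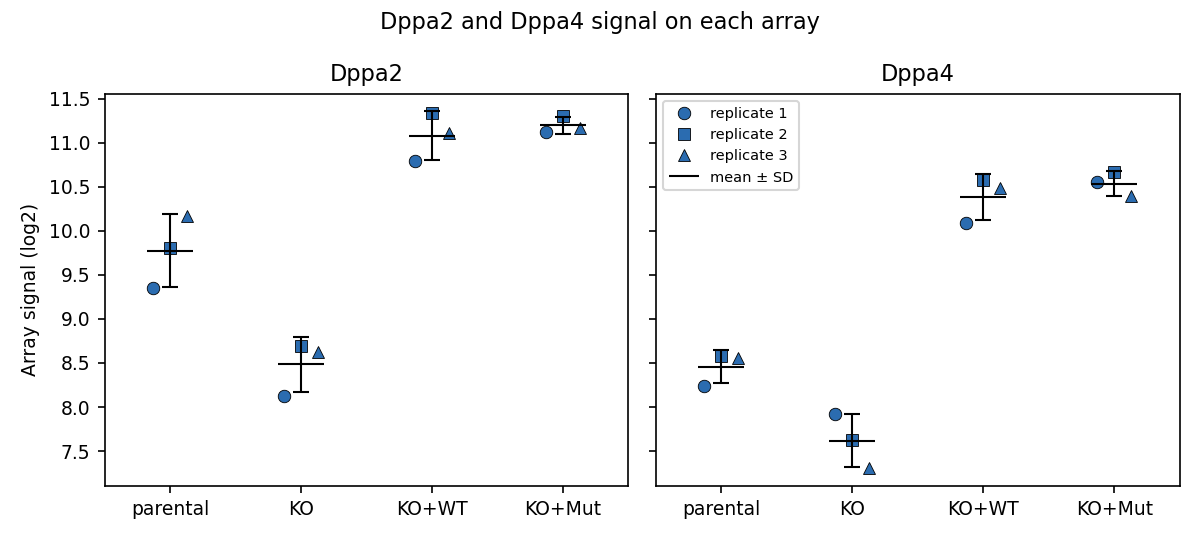
Dppa2 (left) and Dppa4 (right) signal (log2) on each of the 12 arrays by group, with replicates as circles, squares and triangles and black bars for the mean ± SD (n = 3). All KO arrays lie below all parental arrays for both genes, and all add-back arrays lie above them.

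The comparison of KO with parental cells asked which transcripts depend on Dppa2 and Dppa4. Of the 45 genes lower in KO cells 3 belonged to the 2C-like list, 5 to the germline list and 36 to no list. All lists together held 446 measured entries, against 22180 genes tested. Zscan4e, of a family transcribed in 2-cell embryos, fell by 4.41 (log2, SE 0.45, n = 3 arrays per group, adjusted p = 0.000747), and the deubiquitinase gene Usp17le fell by 2.99 (SE 0.32). The splicing factor gene Prpf39 fell by 3.43 (SE 0.15, adjusted p = 1.49e-07). Across 22180 genes, 45 were lower and 8 higher in KO cells, of which 27 and 2 changed at least 2-fold. Among the other genes past the threshold with large falls were Pramel19 (-3.29), the germline transcription factor gene Sohlh2 (-2.54), Gm5662 (-2.20), the Y-linked ubiquitin-activating enzyme gene Uba1y (-2.20), Atxn1l (-2.09), the carbonic anhydrase gene Car4 (-1.85) and the T-cell receptor subunit gene Cd3e (-1.77). A second probe set of Gm5662 differed by -0.70. Of the 8 higher genes 2 were uncharacterised transcripts, and the other 6 were Sult4a1 (0.81), Ccdc38 (0.77), Sdr39u1 (0.77), Sh3bgrl (0.72), the tRNA exporter gene Xpot (0.70) and Zfp40 (0.64). With the replicate number as a block, 97 genes were lower and 40 higher. Leaving out any 1 of the 6 arrays gave 18 to 29 lower and 0 to 3 higher, and in such fits 10 of the 13 falls named besides Dppa2, whose losses are given above, and 0 of the 6 named rises were kept throughout. The falls of Gm5662, Pramel19 and Syce1 were kept in 0, 4 and 3 of the 6 fits. Their adjusted p ran up to 0.192, 0.0515 and 0.068 (without parental replicate 2, KO replicate 1 and KO replicate 2). With array weights 113 were lower and 26 higher, and in the fit of these 6 arrays alone 26 were lower and 1 higher.

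Of the 46 measured genes of the 2C-like list, which holds genes of 2-cell embryos and of the rare stem cells that resemble them, 3 fell (Zscan4e, Usp17le and Gm5662), 43 did not pass and 11 fell when adjusted over the list alone. With the replicate block 6 fell. The call of Gm5662 was kept in 0 of 6 fits without an array, and those of Zscan4e and Usp17le in all 6. The list mean (log2) was 2.86 ± 0.07 in KO and 3.51 ± 0.17 in parental cells (SD, n = 3), lower in all 3 number pairs, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. The list was lower by camera (adjusted p = 2.41e-07, median -0.31, 34 of 46 genes negative), but not past the threshold with its between-gene correlation estimated from the data (adjusted p = 0.315 with an estimated correlation). Of 46 germline and meiosis genes, 5 fell, among them Sohlh2, the helicase gene Ddx4 (-1.41, SE 0.16), the RNA-binding protein gene Dazl (-1.35, SE 0.17) and the synaptonemal complex gene Syce1 (-1.45). Adjusted over the list alone 10 fell and 2 rose, and the median was -0.01. That list's camera adjusted p was 0.0269, and 0.0966 with an estimated correlation; it was 0.0752 with the replicate block, 0.0588 without parental replicate 2 and 0.0551 without KO replicate 2. None of the 24 endoderm markers passed on its own, 10 fell adjusted over the list alone, and 22 were lower in KO (median -0.44, camera adjusted p = 2.16e-12; adjusted p = 0.0308 with an estimated correlation, and 0.0818 with the block and an estimated correlation). Lamb1 and Lama1, which encode laminin chains of the basement membrane, differed by -0.76 and -0.73, and Sox7 by -0.77 (adjusted p = 0.0914, 0.228 and 0.197). With the replicate block 2 endoderm markers fell, Lama1 (0.0227) among them, and the adjusted p of Zscan4b (-2.82, SE 0.56, adjusted p = 0.0741) was 0.0297. The mean of the endoderm list was 5.54 ± 0.12 in KO and 6.02 ± 0.21 in parental cells.

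Other lists shifted in KO cells by camera, with no member past the threshold without the replicate block except Dppa2 in the Dppa family list. With the block the intermediate filament gene Vim of the fibroblast list (-0.45, adjusted p = 0.0387) and Peg10 of the trophectoderm and imprinted lists (-0.55, 0.0427) fell, and Cth of the ATF4 list rose (0.67, 0.0237). Fibroblast markers were lower (median -0.13, 21 of 24 negative, adjusted p = 0.00501; adjusted p = 0.1 with an estimated correlation), as were trophectoderm markers (16 of 23 negative, 0.0229; adjusted p = 0.315 with an estimated correlation), and genes of the ATF4 and unfolded protein response were higher (median 0.18, 24 of 31 positive, 0.00958; adjusted p = 0.478 with an estimated correlation). The 7 measured X-inactivation and Y-linked genes had an adjusted p of 0.0269, and 0.112 with an estimated correlation; it was 0.0752 with the block. The Dppa family list of 5 genes, which holds both targeted genes, had an adjusted p of 0.00455 (1 fell, 3 adjusted over the list alone; adjusted p = 0.0966 with an estimated correlation). The trophectoderm value was 0.0779, 0.0894 and 0.209 without parental replicates 1 and 2 and KO replicate 3, and the X and Y value was 0.113, 0.0825 and 0.0708 without parental replicate 2 and KO replicates 1 and 3. The ATF4 value was 0.447 without KO replicate 1 and the fibroblast value 0.0779 without parental replicate 1. Naive pluripotency genes (median 0.01, adjusted p = 0.703), formative and primed pluripotency genes (0.0673), mesoderm (0.703), interferon response (0.879), p53 targets (0.0673), immediate early and heat shock genes (0.339), imprinted genes (0.129) and SUMO pathway genes (0.729) did not pass, and neuroectoderm, with an adjusted p of 0.05, did not pass either. Among the imprinted genes Grb10, a signalling adaptor, differed by 2.06 (SE 0.46, adjusted p = 0.13), and its adjusted p was 0.000236 with the replicate block. The block also brought past the threshold the imprinted gene Phlda2 (0.88, adjusted p = 0.0186) and, of the formative and primed list, Dnmt3b (-0.86, 0.00439) and Sfrp2 (-0.76, 0.0279).

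**Figure D2:**
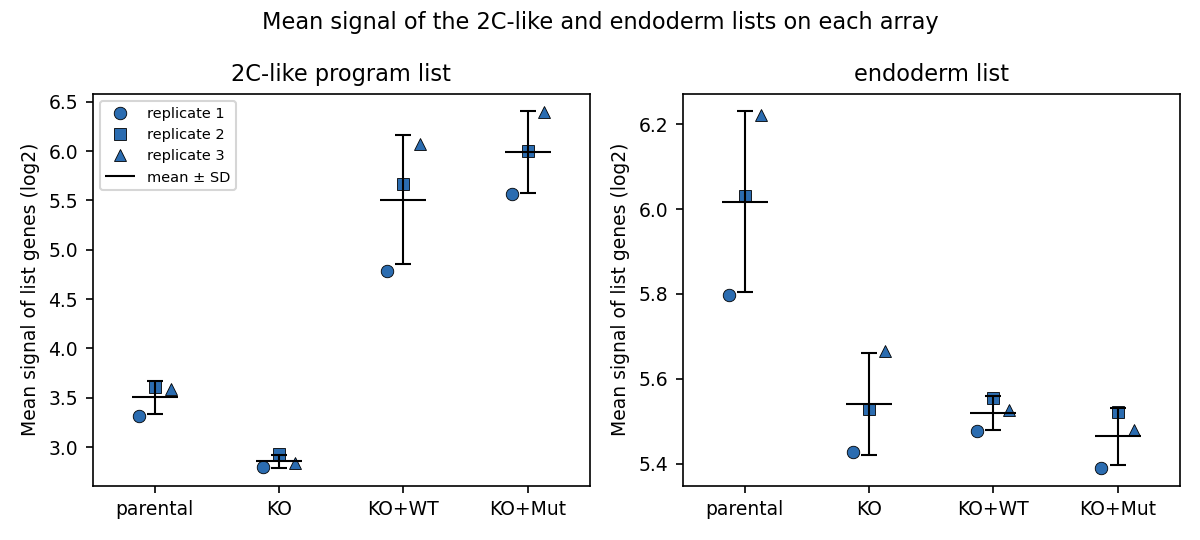
Mean signal (log2) of the 46 genes of the 2C-like list (left) and the 24 genes of the endoderm list (right) on each of the 12 arrays, with replicates as symbols and black bars for the mean ± SD (n = 3); the vertical scales differ. The 2C-like means were 3.51 in parental, 2.86 in KO, 5.51 in KO+WT and 5.99 in KO+Mut cells, and the endoderm means were 6.02, 5.54, 5.52 and 5.46.

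Adding back the wild-type proteins asked which transcripts respond to them in KO cells. Leaving out predicted genes outside the lists, the largest rise was that of Zscan4e, by 8.49 (log2, SE 0.45, n = 3 per group, adjusted p = 1.17e-06), from 2.06 to 10.55, followed by Pramel19, which is outside the 2C-like list, by 7.63 (SE 0.46), Usp17le by 7.02 (SE 0.32) and Zscan4b by 6.95 (SE 0.56). The KO levels of these genes lay near the lower quartile of the arrays, 2.36 to 2.47, where log2 differences can understate a change. Further large rises were those of Gm5662 (6.23), the POZ-domain gene Tdpoz3 (6.11), Gm2022 (6.05), Zscan4c (5.77), Eif4a3l1 (5.63) and Gm4340 (5.47). In all, 162 genes were higher and 22 lower, of which 100 and 5 changed at least 2-fold. Among genes past the threshold whose groups did not overlap, leaving out predicted, uncharacterised, microRNA and small nucleolar RNA genes, the largest falls were those of the vault RNA gene Vaultrc5 (-1.11), Map7d3 (-1.02), the stearoyl-CoA desaturase gene Scd1 (-0.96), Ddx25 (-0.83), Gtsf1l (-0.80), the pluripotency factor gene Prdm14 (-0.78), Rab8b (-0.75), Ndufb11 (-0.74), Zfp606 (-0.65) and Srgn (-0.65), with adjusted p between 0.00824 and 0.0499. The shares of higher calls were 88% as deposited and 75.2% after centring each array on its median (112 higher, 37 lower). The array medians over all probe sets were on average 0.077 (log2) higher in KO+WT than in KO. The count of higher genes was 104, 80 and 86 without KO replicates 1, 2 and 3, and 83 without KO+WT replicate 2; that of lower genes was 6 to 12 whichever of the 6 arrays was left out, and none of the 10 named falls was kept in all of these fits. In the fit of these 6 arrays alone 71 were higher and 4 lower, and with the replicate number as a block 353 were higher and 141 lower.

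Of the 46 genes of the 2C-like list 22 rose with wild-type add-back, 24 did not pass, and 30 rose when adjusted over the list alone. The list mean was 5.51 ± 0.66 against 2.86 ± 0.07 in KO cells (SD, n = 3, exact permutation p = 0.1, two-sided), and 43 of 46 genes were positive (median 2.58, camera adjusted p = 9.47e-46; adjusted p = 0.0394 with an estimated correlation). Near-identical members of the Zscan4, Usp17l, Tdpoz, Tcstv and Pramel families may share probes, so that their values are not independent. Of the germline list 4 genes rose: Dazl by 1.69, Ddx4 by 1.25, the sperm mitochondrial carrier gene Slc25a31 by 0.85 and the piRNA helicase gene Mov10l1 by 1.03 (10 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.149). The call of Mov10l1 was kept in 1 of the 6 fits without an array, the highest adjusted p being 0.106 without KO replicate 2. Of 32 naive pluripotency genes Fbxo15 rose (0.79) and Prdm14 fell (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0796). Srgn was the endoderm gene that fell (1 rose and 1 fell over the list alone; adjusted p = 0.911), Ddit4l (1.14) was the p53 target that rose (0.0825) and Jun, a subunit of the AP-1 transcription factor, rose by 1.04 in the immediate early list (0.149). The calls of Ddit4l and Jun were kept in 2 and 1 of the 6 fits without an array, with adjusted p up to 0.15 (without KO replicate 2) and 0.159 (without KO+WT replicate 2). Lists of small shifts without a member past the threshold were SUMO pathway and silencing genes (29 of 32 negative, median -0.13, adjusted p = 0.00141; adjusted p = 0.218 with an estimated correlation), mesoderm (17 of 24 positive, 0.0184; adjusted p = 0.163 with an estimated correlation) and fibroblast markers (20 of 24 positive, 0.0483; adjusted p = 0.218 with an estimated correlation). Without KO replicate 3 the values were 0.061, 0.09 and 0.0828 in that order. The mesoderm value was 0.0631 without KO+WT replicate 2, and the fibroblast value was 0.131 without KO replicate 2 and 0.0969, 0.0631 and 0.0577 without KO+WT replicates 1, 2 and 3. The endoderm mean of 5.52 ± 0.04 in KO+WT differed from that of KO cells by -0.02 (exact permutation p = 0.8, two-sided).

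Adding back the SUMO-deficient proteins moved many of these genes. Zscan4e rose by 9.04 over KO (log2, SE 0.45, n = 3 per group, adjusted p = 5.39e-07), Pramel19 by 8.24 (SE 0.46), Zscan4b by 7.81 (SE 0.56) and Usp17le by 7.40 (SE 0.32). Further large rises were those of Tdpoz3 (7.19), Gm5662 (6.77), Gm2022 (6.59), Zscan4c (6.42), Eif4a3l1 (6.27) and Gm4340 (5.94). In all, 248 genes were higher and 34 lower, of which 142 and 5 changed at least 2-fold. Among genes past the threshold chosen in the same way, the largest falls were those of Accsl (-1.10), Scd1 (-1.01), Slco4c1 (-0.95), the arginine methyltransferase gene Prmt8 (-0.91), Ddx25 (-0.86), Zfp874b (-0.85), Map7d3 (-0.79), Zglp1 (-0.74), Srgn (-0.73) and Scd3 (-0.71). The share of higher calls was 87.9%, and 72.9% after centring each array on its median (194 higher, 72 lower). The array medians over all probe sets were on average 0.08 higher in KO+Mut than in KO. The count of higher genes was 158, 158 and 159 without KO replicates 1, 2 and 3 and 109 without KO+Mut replicate 2, and that of lower genes was 10 to 19 whichever of the 6 arrays was left out. Array weights gave 432 higher and 96 lower, and in the fit of these 6 arrays alone 12 were lower. The replicate number as a block gave 480 higher and 236 lower.

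Of the 46 genes of the 2C-like list 28 rose with mutant add-back, 18 did not pass and 33 rose adjusted over the list alone. The list mean was 5.99 ± 0.41 (SD, n = 3; exact permutation p = 0.1 against KO, two-sided), and 41 of 46 genes were positive (median 3.12, camera adjusted p = 5.93e-54; adjusted p = 0.0238 with an estimated correlation). Of the germline list 5 genes rose, among them Dazl (1.80), Ddx4 (1.40), Slc25a31 (0.94) and Tdrd6 (0.89) (9 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.0543). Of the immediate early and heat shock list 3 of 23 genes rose: Hspa1b (1.40, SE 0.20) and Hspa1a (1.15), which encode inducible HSP70, and Jun (1.25). For this list 6 rose adjusted over the list alone, with camera adjusted p = 0.00619, and adjusted p = 0.128 with an estimated correlation. Among imprinted genes 2 of 27 rose, Ascl2 (0.84), a trophoblast transcription factor gene that is also the trophectoderm gene that rose, and Dlk1 (1.10). The imprinted list had an adjusted p of 0.0346, and adjusted p = 0.318 with an estimated correlation. Fbxo15 rose by 1.13 and Prdm14 fell by 0.70 among naive pluripotency genes (0.0515), and Ddit4l (1.33) and the endoplasmic reticulum chaperone gene Dnajb9 (0.80) rose among p53 targets (0.15) and ATF4 genes (0.893). Of the 11 falls named, those of Accsl, Ddx25 and Zfp874b were kept in every fit without an array. The calls of Tdrd6, Ddit4l, Prdm14 and Jun were kept in 3, 3, 2 and 5 of the 6 such fits (adjusted p up to 0.0898, 0.0734, 0.107 and 0.0777, without KO+Mut replicate 2). Those of Hspa1a, Dlk1 and Dnajb9 were kept in 1, 2 and 2 (up to 0.145, 0.0839 and 0.0997, without KO replicates 1, 3 and 2).

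Smaller shifts with mutant add-back were those of SUMO pathway and silencing genes (27 of 32 negative, adjusted p = 0.00834; adjusted p = 0.318 with an estimated correlation), fibroblast markers (18 of 24 positive, 0.0195; adjusted p = 0.153 with an estimated correlation) and neuroectoderm genes (15 of 23 positive, 0.0425; adjusted p = 0.221 with an estimated correlation). Without KO replicate 3 the SUMO, neuroectoderm and imprinted values were 0.143, 0.12 and 0.143, and without KO+Mut replicate 1 they were 0.0628, 0.0773 and 0.0959. The neuroectoderm value was also above the threshold without KO replicate 2 (0.109) and KO+Mut replicate 3 (0.0792), and the imprinted value without KO+Mut replicate 2 (0.108). The Dppa family lists were higher than in KO with wild-type and mutant add-back (0.0184 and 0.00834; adjusted p = 0.163 and 0.128 with an estimated correlation), through Dppa2 and Dppa4 themselves, and without KO+WT replicate 3 the first was 0.0624.

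**Figure D3:**
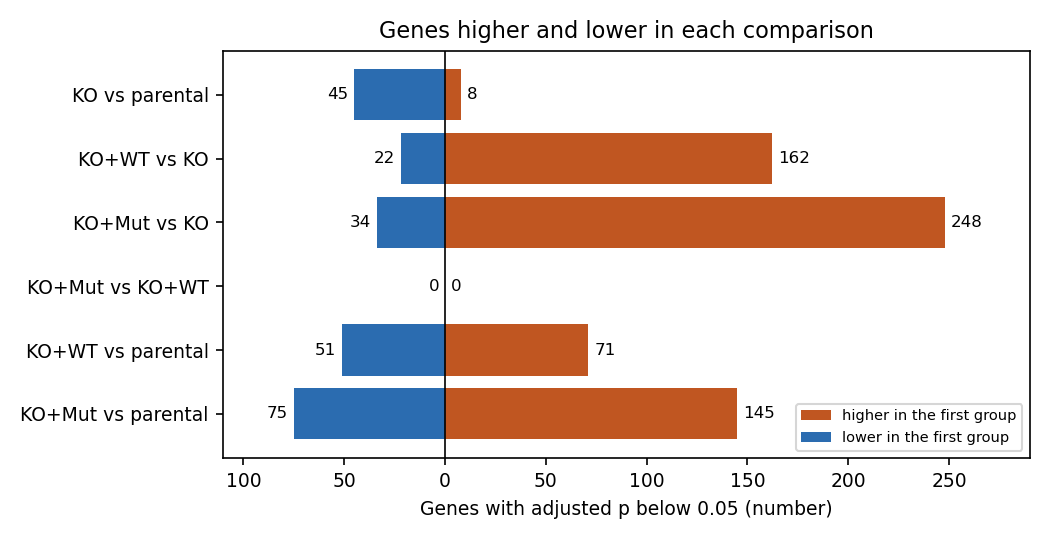
Number of genes with a limma adjusted p below 0.05 in each of the 6 comparisons, with genes higher in the first-named group to the right of 0 and lower genes to the left. The bars run from 0 in KO+Mut against KO+WT to 248 higher in KO+Mut against KO.

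The calls of both add-backs against KO overlapped. Of the 162 and 248 higher genes 139 were shared, where independent lists of those sizes would share 1.81, and of the 22 and 34 lower genes 13 were shared (0.0337 by the same reckoning). The shared higher genes included 22 of the 2C-like list, and 31 lay in any fixed list. The log2 changes correlated with r = 0.881 across genes, which are not independent replicates, where unchanged groups simulated against the same KO arrays gave 0.5. The covariance was 0.103 against a simulated 0.016, a difference of 0.087. Because the KO arrays were shared, part of the overlap may come from them. The shared higher count was 75 to 148 whichever array was left out, and the shared lower count 1 to 7. With the replicate number as a block they were 269 and 84.

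The matched comparison of the add-backs asked what the SUMO sites change. No gene passed the threshold in limma, with 675 genes at an unadjusted p under 0.05 where 1109 would be reached by chance, and 0 genes passed with the replicate block (1214 at an unadjusted p under 0.05), with array weights or with trend and robust variances. The smallest adjusted p, 0.0832, was that of Gucy1a1, a guanylate cyclase subunit gene, at -0.98 (log2, SE 0.13, n = 3 per group). The other genes of smallest p were Crb1 (-0.73, SE 0.14), Serpina1b (-0.44, SE 0.10), the phosphatase gene Dusp10 (0.58, SE 0.12), Duxf3 (1.31, SE 0.28), of the DUX homeobox family that activates 2-cell genes, and Ascl2 (0.55, SE 0.13), all with adjusted p = 1. In the simulated data 92% of genes changed by 1 (log2) and 12% of those changed by 0.5 were recovered in this comparison. Those data held 50 planted genes at each size up to 3, which makes the adjusted threshold easier to pass than where no gene passes. The shares therefore do not carry over to the real comparison. Small differences were not excluded, and neither were larger ones such as that of Duxf3 (1.31).

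Lists of genes nonetheless lay to one side. In the 2C-like list 36 of 46 genes were higher in KO+Mut, with a median difference of 0.50, and 1 was higher adjusted over the list alone. Tdpoz4 differed by 1.12 (SE 0.30) and Tdpoz3 by 1.08 (SE 0.41). Camera gave an adjusted p of 4.21e-10, with adjusted p = 0.434 with an estimated correlation and 0.79 by fry. The list means of 5.99 ± 0.41 and 5.51 ± 0.66 (SD, n = 3) gave an exact two-sided permutation p of 0.5, although KO+Mut was higher in all 3 number pairs, by 0.781, 0.339 and 0.321. Without KO+WT replicate 1 the camera adjusted p was 0.211. The immediate early and heat shock list was higher (19 of 23 positive, 1 adjusted over the list alone, adjusted p = 0.0126; adjusted p = 0.409 with an estimated correlation), with Hspa1b at 0.85 (SE 0.20) and Hspa1a at 0.73 (SE 0.25), and its adjusted p was 0.361 without KO+WT replicate 1 and 0.0544 without KO+Mut replicate 3. No other list passed, the adjusted p being 0.562 for SUMO pathway genes, 0.429 for endoderm, 0.452 for germline genes, 0.913 for naive pluripotency genes, 0.692 for fibroblast markers and 0.745 for interferon genes. Over the 139 genes higher in both add-backs, 108 were nominally higher in KO+Mut, with a median difference of 0.19 against a median 95% half-width of 0.43.

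The genes that had changed in KO cells were followed into the add-backs. Of the 45 lower genes 16 rose over KO with wild-type and 17 with mutant add-back, 16 of them in both. Independent lists would share 0.329 and 0.503, but both calls rest on the same KO arrays, so part of the overlap may come from chance values of those arrays. Of the 45 genes 7 were higher than parental cells in both add-backs, among them Dppa2, Zscan4e, Usp17le, Pramel19 and Gm5662, and other genes lay near the parental level. Dazl was 0.35 and 0.45 above parental, Ddx4 -0.16 and -0.01, Slc25a31 0.08 and 0.17, Dmrtb1 0.31 and 0.41, Homer2 0.36 and 0.34, Epb41l3 0.36 and 0.29 and the calmodulin-dependent kinase gene Camk2b -0.03 and 0.00 in KO+WT and KO+Mut. Car4 recovered 47.5% and 38.3% of its fall. Another 28 genes rose in neither add-back, and 16 of these stayed lower than parental cells in both. The 28 had been chosen for lying below the same parental arrays and for not rising, so that count follows in part from the choice. Prpf39 stayed at -3.71 and -3.23, Atxn1l at -2.09 and -1.91, Uba1y at -1.79 and -1.88, Sohlh2 at -1.72 and -1.71, the polycomb gene Scml2 at -1.62 and -1.63, Nxf7 at -1.63 and -1.42, the glycine decarboxylase gene Gldc at -1.16 and -1.34 and Klhl13 at -1.27 and -1.13. None of the 8 genes higher in KO fell in either add-back by limma, although all 8 were nominally lower (median -0.41 and -0.35, from KO arrays that also defined the set). Across all genes the KO changes correlated with the add-back changes at r = -0.508 and -0.490, where unchanged groups sharing the KO arrays gave -0.5, and the covariances differed from the simulated ones by -0.021 and -0.022. The counts of 16 and 17 were 6 to 17 and 6 to 13 when single arrays were left out. With the replicate number as a block 97 genes were lower in KO, of which 40 and 41 rose.

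**Figure D4:**
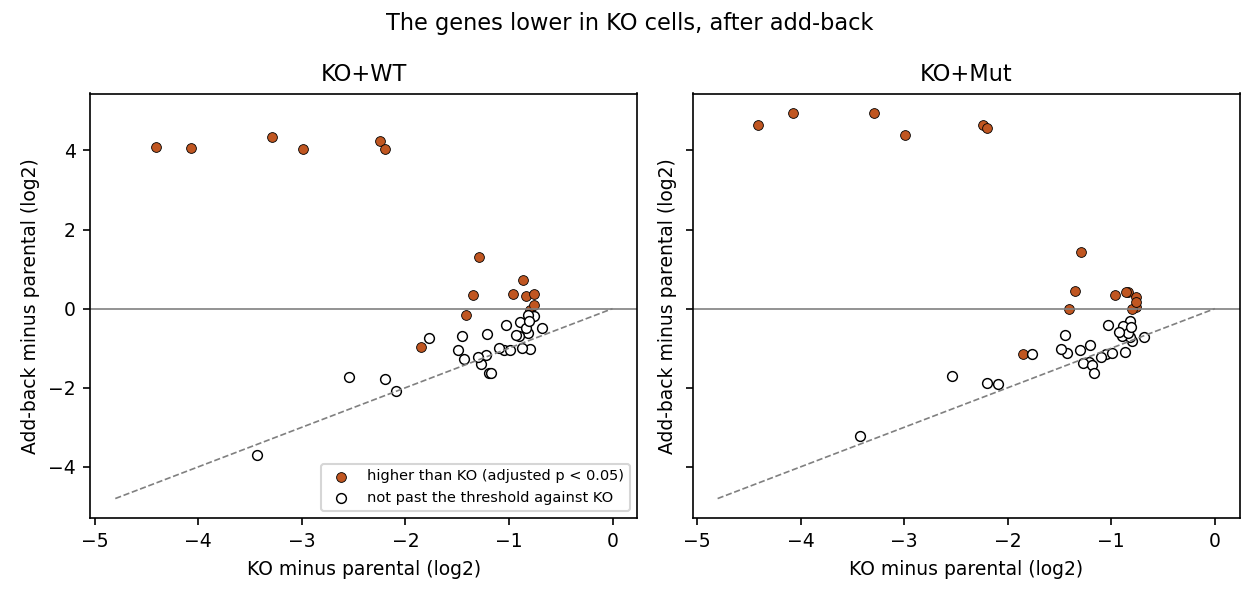
The 45 genes lower in KO than in parental cells, with KO minus parental (log2) across and add-back minus parental (log2) up, for KO+WT (left) and KO+Mut (right); filled points rose over KO, the solid line is the parental level and the dashed line marks no change from KO. In both panels 6 points lie more than 4 above the parental level, while Prpf39 lies near the dashed line at -3.71 and -3.23.

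As sets, the genes lower in KO did not differ between the add-backs (24 of 45 higher in KO+Mut, median 0.02, camera adjusted p = 0.333), except without KO replicate 2, where the set shrank and the adjusted p was 0.00779. The 8 genes higher in KO were all nominally higher in KO+Mut than in KO+WT (median 0.09, adjusted p = 0.0308; adjusted p = 0.204 with an estimated correlation). That call was lost after repeated quantile normalization (0.0877) and turned direction with the replicate block (0.482), under which the set held 40 genes. Of the 9 fits without 1 array that left a set to test, the call was kept without KO+Mut replicate 1 (0.0357) and lost in the other 8, with adjusted p from 0.0679 without KO+Mut replicate 2 to 0.4 without parental replicate 3.

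Relative to parental cells, 21 of the 46 genes of the 2C-like list were higher in KO+WT and 29 in KO+Mut, and 17 of the 45 genes lowered in KO were lower in both add-backs. Those 45 genes had been chosen against the same parental arrays, so part of the 17 may come from chance values of those arrays. Tdpoz3 was 4.49 higher in KO+WT (log2, SE 0.41, n = 3 per group) and 5.57 in KO+Mut, Pramel19 4.35 and 4.95, Gm2022 4.31 and 4.85 and Zscan4b 4.13 and 4.99, with Gm4340 at 4.11 in KO+WT and Gm8300 at 4.71 in KO+Mut. Among genes past the threshold, the largest falls in both were those of Prpf39 (-3.71 and -3.23, highest adjusted p = 3.17e-07), Atxn1l, Uba1y, Sohlh2 and the FGF co-receptor gene Klb (-1.89 and -2.17). With wild-type add-back 71 genes were higher and 51 lower than in parental cells, and with mutant add-back 145 and 75. The shares of higher calls were 58.2% and 65.9%, and 48.8% and 52.8% after centring each array on its median (59 higher and 62 lower in KO+WT, 122 and 109 in KO+Mut). The block gave 237 and 221 genes for KO+WT and 353 and 342 for KO+Mut. Leaving out any parental array gave 34 to 37 higher genes in KO+WT and 76 to 82 in KO+Mut, KO+WT replicates 2 and 3 gave 36 and 40, and KO+Mut replicates 2 and 3 gave 70 and 91. Lower genes numbered 16 to 31 and 34 to 59 over all arrays left out, and array weights gave 113 higher in KO+WT and 282 higher and 173 lower in KO+Mut. The call of Klb in KO+WT was kept in 1 of the 6 fits without an array (adjusted p up to 0.111, without parental replicate 3).

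Of the 2C-like list 21 genes were higher than in parental cells with wild-type and 29 with mutant add-back (33 and 34 adjusted over the list alone, with 2 lower in KO+Mut; camera adjusted p = 7.5e-42 and 5.63e-51; adjusted p = 0.0285 and 0.0284 with an estimated correlation). Endoderm markers were below parental cells in both (3 fell in each, 6 in each with the block, 8 and 11 adjusted over the list alone, camera adjusted p = 6.12e-08 and 1.26e-09; adjusted p = 0.0411 and 0.0357 with an estimated correlation, and 0.0717 and 0.0654 with the block as well). Srgn fell by 1.23 and 1.31, Lamb1 by 0.92 and 0.95 and Lama1 by 0.94 and 0.95. The KO+WT calls of Lamb1 and Lama1 were kept in 2 and 1 of the 6 fits without an array (adjusted p up to 0.0902 and 0.194, without parental replicate 2). In KO+Mut those of Lamb1 and Lama1 were kept in 5 and 1 (up to 0.0527 and 0.141, without KO+Mut replicate 3 and parental replicate 3). Genes of the p53 list were higher (22 and 21 of 27 positive, adjusted p = 0.000554 and 0.00404; adjusted p = 0.181 and 0.251 with an estimated correlation), with Ddit4l higher in KO+Mut (1.22) and 3 genes higher in each with the block. The call of Ddit4l was kept in 1 of 6 such fits (up to 0.128, without KO+Mut replicate 2). SUMO pathway genes were lower (0.000159 and 0.00263; adjusted p = 0.181 and 0.268 with an estimated correlation, the first being 0.0448 with the block as well). The X and Y list was lower in KO+WT (0.00027; adjusted p = 0.0285 with an estimated correlation and 0.0546 with the block as well), with Kdm5d at -1.01 from a parental level of 2.93. The Kdm5d call was kept in 1 of 6 such fits (up to 0.13, without parental replicate 2). In KO+Mut the list's adjusted p was 0.0241 (adjusted p = 0.144 with an estimated correlation, and 0.077 without parental replicate 2). Grb10 rose by 2.31 and 2.36 over parental cells. Both calls were kept in 1 of 6 such fits (up to 0.182 without parental replicate 3 and 0.143 without KO+Mut replicate 2). Mesoderm genes had an adjusted p of 0.0319 in KO+WT (19 of 24 positive; adjusted p = 0.181 with an estimated correlation), and 0.0637 and 0.102 without parental replicate 1 and KO+WT replicate 2.

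In KO+Mut 3 genes of the immediate early and heat shock list were above parental cells, Hspa1b (1.31, SE 0.20), Hspa1a (1.28, SE 0.25) and Fos (0.94, SE 0.18), the last a partner of Jun in AP-1. The call of Hspa1b was kept in all 6 fits without an array. Those of Hspa1a and Fos were kept in 1 each (adjusted p up to 0.136 without parental replicate 3 and 0.12 without KO+Mut replicate 2). The list had an adjusted p of 0.0241 (13 of 23 positive, 5 rose and 1 fell adjusted over the list alone; adjusted p = 0.235 with an estimated correlation), 0.12 with the replicate block, 0.0671 without parental replicate 1 and 0.0658 without KO+Mut replicate 3. Genes of the ATF4 and unfolded protein response had 0.0241 (22 of 31 positive, 1 rose, 3 with the block, 2 adjusted over the list alone; adjusted p = 0.633 with an estimated correlation), and 0.1, 0.565 and 0.0506 without parental replicate 3 and KO+Mut replicates 1 and 2. In KO+WT the same ATF4 list had 0.0622, and 0.0049 with the replicate block (adjusted p = 0.409 with the block and an estimated correlation). The Dppa family list in KO+Mut had 0.0475 (adjusted p = 0.235 with an estimated correlation), 0.0942 with the block, and 0.077, 0.0837, 0.0529 and 0.0651 without parental replicate 2 and KO+Mut replicates 1, 2 and 3.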

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

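Of the tests weighed in this part, the one on Dppa2 and Dppa4 transcript and the one without a single KO+WT array were chosen only after the result was seen.

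The 2C-like list was higher in KO+Mut than in KO+WT by camera with its preset correlation (adjusted p = 4.21e-10, mean difference 0.48 log2, KO+Mut higher in 3 of 3 number pairs), a call lost with an estimated correlation (adjusted p = 0.434) and by fry (0.79). Averaging 6 families to 1 value each, which left 25 entries for the 46 genes, gave an adjusted p of 6.24e-09 with the preset correlation. Counting members of those 6 families as separate genes was therefore not needed for that call. Other genes such as Gm5662 and Gm2022 stayed separate entries, and the list's estimated correlation was 0.326, above the preset. The test therefore cannot decide whether values that are not independent caused the call. Without KO+WT replicate 1, whose list mean was 4.79 against 5.66 and 6.07 on the other KO+WT arrays, the difference of means dropped to 0.119. Replicate 1 was also the lowest KO+Mut array (5.57), and without replicate 1 of either add-back the difference was 0.33. A single low array may account for part of the pattern, and how large a part stays open. More Dppa2 and Dppa4 transcript in KO+Mut cannot be told apart from an effect of the SUMO sites, because the difference of 0.13 had a 95% interval of -0.26 to 0.53. That interval did not use the number pairs. By pair the mean of Dppa2 and Dppa4 differed by 0.40, 0.03 and -0.02, where the 2C-like list mean differed by 0.781, 0.339 and 0.321. The transcript difference thus lay mostly in pair 1, but 3 pairs are too few to decide. The effect of the SUMO sites itself stays open.

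The immediate early and heat shock list passed the same test between the add-backs (adjusted p = 0.0126, median 0.08, 19 of 23 genes higher in KO+Mut). The call was lost with an estimated correlation (adjusted p = 0.409), without KO+WT replicate 1 (0.361) and without KO+Mut replicate 3 (0.0544). The 8 genes higher in KO passed it as a set (adjusted p = 0.0308, median 0.09, 8 of 8 higher in KO+Mut). That call was lost with an estimated correlation (adjusted p = 0.204), by fry (0.247) and in 8 of 9 fits without 1 array (up to 0.4, without parental replicate 3), and the direction turned with the replicate block (0.482).

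Probe sets with no gene symbol or several, which no comparison of named genes used, also passed the threshold. In KO against parental cells, 1 with no symbol was lower, and 1 with several was higher and 13 lower. With wild-type add-back against KO, 42 with no symbol were higher and 5 lower, and 70 with several were higher and 1 lower. With mutant add-back against KO, 59 with no symbol were higher and 4 lower, and 85 with several were higher and 5 lower.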

How the results depend on the processing

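All alternatives were planned and run. Among named genes, 5796 values under alternatives kept direction and side of the threshold, 281 dropped below it and 120 passed it. Another 3 changed direction with neither value past the threshold, and 0 changed direction with either value past it. Many of these values belong to list members not past the threshold, so the counts do not measure how stable the calls were. Of the genes named as past it, 14 of 17 rises and 0 of 10 falls in KO+WT against KO were kept in every fit without an array. For KO+Mut against KO they were 16 of 22 and 3 of 11. Among the lists not tested as main results 966 kept both, 98 dropped below and 45 passed. For these lists 69 changed direction with neither value past the threshold, and 0 with either value past it. The counts of lists likewise include lists that were not past the threshold to begin with. KO signals near the lower quartile, such as those of Zscan4e and Zscan4b, limit how large a fold can be measured. The cause of the changes below was not tested, except that a fold limit and fits of fewer arrays call fewer genes by construction.

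With the replicate number as a block, counts of higher and lower genes were 40 and 97 for KO against parental, 353 and 141 for KO+WT against KO, 480 and 236 for KO+Mut against KO, 237 and 221 for KO+WT and 353 and 342 for KO+Mut against parental. Genes lower in KO that rose in KO+WT and KO+Mut numbered 40 and 41, and genes higher and lower in both add-backs 269 and 84. The set of genes higher in KO turned direction between the add-backs (adjusted p = 0.482). For the add-backs against KO the numbers were not taken to pair the arrays, because replicate 2 correlated below the 0.1 limit (0.31, 0.06 and 0.29, and 0.31, 0.08 and 0.36). That limit alone decided this. All of these correlations were positive, and 12 of 12 arrays correlated best with their own number in other groups, a hint from the data and not the design. A pairing of those arrays was therefore not excluded. For the lists, the block ended the calls of imprinted genes (adjusted p = 0.0601) and neuroectoderm (0.0763) in KO+Mut against KO. It brought past the threshold naive pluripotency there (0.0371, but 0.255 with an estimated correlation as well) and p53 targets in KO+WT against KO (0.0312, but 0.467 with an estimated correlation as well). Beyond these, the block values beside results in the report and calls of single genes, the block changed no other camera call of a list and no other result of a comparison.

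In fits of the 6 arrays compared, counts were 1 higher and 26 lower for KO against parental, 71 and 4 for KO+WT against KO, 12 lower for KO+Mut against KO, and 32 and 20 for KO+WT against parental. Dppa2 then differed by -1.29 in KO (adjusted p = 0.126) and 1.31 in KO+WT against parental (0.0839). With a 2-fold limit they were 2 and 27 for KO against parental, 100 and 5 for KO+WT and 142 and 5 for KO+Mut against KO, and 24 and 29 lower for KO+WT and KO+Mut against parental. Over all probe sets they were 4 and 27 for KO against parental, and 126 and 248 higher for KO+WT and KO+Mut against parental. With array weights they were 26 and 113 for KO against parental, 432 and 96 for KO+Mut against KO, 113 higher for KO+WT and 282 and 173 for KO+Mut against parental, and Dppa4 in KO passed at -0.83 (adjusted p = 0.0289). Median centring gave 37 and 72 lower for KO+WT and KO+Mut against KO. The 2C-like list had 0.268 by fry and 0.315 with an estimated correlation for KO against parental, and 0.79 and 0.434 for KO+Mut against KO+WT. The set of genes higher in KO had 0.247, 0.204 and, with quantile normalization again, 0.0877.

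Leaving out 1 array gave 0 to 3 higher and 18 to 29 lower for KO against parental, 80 to 154 and 6 to 12 for KO+WT against KO, 109 to 192 and 10 to 19 for KO+Mut against KO, 34 to 102 and 16 to 31 for KO+WT against parental, and 70 to 118 and 34 to 59 for KO+Mut against parental. Dppa2 ran from -1.51 to -1.1 in KO against parental, 1.09 to 1.5 in KO+WT against parental and -0.03 to 0.25 between the add-backs. The adjusted p between the add-backs ran from 3.32e-18 to 0.211 for the 2C-like list, 0.00779 to 0.379 for genes lower in KO and 0.0357 to 0.4 for genes higher in KO. Genes lower in KO that rose numbered 6 to 17 in KO+WT and 6 to 13 in KO+Mut, and genes higher and lower in both add-backs 75 to 148 and 1 to 7.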

Other observations

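The tests on the genes that rose in neither add-back were chosen only after the result was seen.

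Most genes that responded to the add-backs lay outside the fixed lists, as do most genes tested. The lists held 446 measured entries, against 22180 genes. Of the 162 genes higher in KO+WT than in KO, 131 were in no list and 31 in a list, and of the 248 for KO+Mut 205 and 43. The lists thus held a larger share of these genes than of all genes. The median rise of all 162 and 248 was 1.12 and 1.17 (log2). The 45 genes lower in KO (median -1.19) included 36 in no list and 9 in a list. The 139 genes higher in both add-backs had a median of -0.5 in KO against parental cells, and the 13 lower in both a median of 0.21. Those values share the KO arrays.

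Of the genes lower in KO, 28 rose in neither add-back, with a median of -1.13 in KO against parental cells. Loss of the whole Y chromosome is argued against by Eif2s3y, whose difference of -0.12 had a lower 95% bound of -0.36, above that median. Uty differed by 0.04 (lower bound -0.37). Other Y-linked genes fell: Kdm5d, from a low parental level of 2.93, differed by -0.73 (95% interval -1.12 to -0.35), and Uba1y, 1 of the 28, by -2.20. Loss of part of the chromosome was not tested. Endoderm-like cells in the parental cultures might account for part of the falls and stay open: the endoderm list fell less than these genes in every number pair, by at least 0.61, but the genes had been chosen for their fall on the same arrays, so that comparison decides nothing. The genes recovered a median of 21.2% in KO+WT and 16.7% in KO+Mut, but they had been chosen for not rising past the threshold. A low recovery follows from that choice and decides nothing. Single genes ran from -38.3% (Scml2) to 80.6% (Castor1) in KO+WT, and 16 of the 28 stayed lower than parental cells in both add-backs. That count also follows in part from the choice, which used the same parental arrays. A clonal or culture difference might leave such falls, as might a lasting change after the loss of Dppa2 and Dppa4. The last pair cannot be told apart, since the labels name no second KO line.

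Of the genes higher in both add-backs than in parental cells, 64 in all, 21 were in the 2C-like list. They had a median of -0.34 in KO against parental cells, and 46 were negative there. Transfection and sorting may have raised them, and this cannot be told apart from an effect of the added proteins without KO cells that went through the same steps.

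With 10 splits of 6 arrays no share under 0.05 can be reached. The real groups gave 53 genes for KO against parental, 184 and 282 for KO+WT and KO+Mut against KO, 122 and 220 against parental, and 0 between the add-backs, with 0 as the highest of the other splits in each comparison, also among splits that part as many number pairs. In the first 5 comparisons 1 of 10 splits gave as many genes as the real one, and between the add-backs 10 of 10.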
